A study of Homo sapiens with 4 samples.

How the data were processed

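RNA sequencing measured transcript levels in cells labelled as MCF-7, an estrogen receptor positive line derived from a human breast cancer, on an Illumina Genome Analyzer. The labels describe 4 groups of 1 library each: wild-type cells and cells with a stable short hairpin against CD24, each grown as a monolayer or as free-floating spheres. Monolayers had 10% serum. Spheres had 20 ng/ml EGF and 10 ng/ml bFGF for 5 days on a non-adhesive coating. Knockdown cells were selected with puromycin at 1 ug/ml and expanded from single cells, per the labels' protocols.

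Tables of 2 libraries were used, monolayer CD24KD and sphere WT. Each table was assigned to its library by the sample title in the table's name, because no other record ties them. The monolayer WT and sphere CD24KD libraries were not analysed here. The 4 comparisons that change only the culture or only the knockdown were therefore not analysed here. The 1 comparison made, sphere WT against monolayer CD24KD, changes culture and knockdown together by its labels. Marker genes given below leave open that the 2 libraries also hold different cells. No difference can be assigned to any of these factors. With 1 library per group there is no replicate error, no test and no p-value.

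The values are FPKM (fragments scaled to transcript length and library size) with a 95% interval and a status for each RefSeq transcript, deposited by the authors as Cufflinks tables. Alignment with TopHat2 2.0.7, quantification with Cufflinks 2.1.1 and build hg18 are listed in the submitters' processing notes. The deposited tables hold 42098 rows of 40775 RefSeq accessions. The RefSeq table of another assembly named 39442 accessions and GENCODE release 29 named 527. The remaining 806 kept their accession. Both references served for names, GC content and length only, and all coordinates are those of the tables in hg18, counted from 1. Rows of 1 symbol were added, giving 24051 genes. The intervals of added rows were combined as the sum of their midpoints and the root of the sum of their squared half-widths.

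The difference was log2 of the sphere WT FPKM plus 1 over the monolayer CD24KD FPKM plus 1, which understates the change of low genes. Positive values mean higher in sphere WT. A gene was tested against the size rule where its status was OK in both libraries and at least 1 library reached 1 FPKM. It was called higher or lower where the difference was 2-fold or more and the 95% intervals did not overlap. The calls compare 2 libraries and not the conditions they stand for.

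Read totals are not in the sources used here, so the depth is unknown. The median half-width of the intervals was 17.3% of the midpoint in monolayer CD24KD and 28.1% in sphere WT. If the intervals hold counting error only, they imply 3.71 times as many fragments in monolayer CD24KD as in sphere WT, so sphere WT was the shallower library by this estimate. Of the rows with the fewest implied fragments, 4.23% of 3786 in monolayer CD24KD and 5.11% of 4030 in sphere WT lay within 0.02 of a whole number, against 4% by chance, so whole reads were not recovered. The FPKM lay outside its own interval in 6225 rows of monolayer CD24KD (26.6% of its rows above 0) and 2432 rows of sphere WT (15.0%). Longer transcripts were affected too, among them genes named below, and not each case is marked there. HMGN5, for example, had 122 FPKM in monolayer CD24KD with an interval of 20.1 to 23.4. For transcripts under 200 nt the FPKM was a median of 23.6 times the interval midpoint in monolayer CD24KD and 24.5 times in sphere WT, and small RNAs were not named for that reason. A value of exactly 0 can be a failed estimate, since genes that every cell uses are also at 0, so such genes are said to be listed at 0 and given no fold.

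Named genes followed a rule fixed before the data were examined. It takes CD24, the 10 genes with the largest difference each way, and up to 4 members of each described list with the largest difference. CD44, VIM, CDH1 and ESR1 are added. The 10 each way needed 10 FPKM or more in 1 library, separate intervals, a locus of 500 bp or more, and a symbol outside the small RNA and LOC families. Here 1 gene that meets the rule is not reported.

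The 37 gene lists were also fixed before the data were examined, and 33 of them had the minimum of 5 members with a value. The median difference of each list was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5, as a description of these libraries. Another 15 lists on cell identity and on regions lost or amplified in MCF-7 were written after the tables were first seen.

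The procedure was tested on simulated data for sphere WT against monolayer CD24KD, drawn from the interval-implied fragments of 11656 genes of which 200 were changed. The rule called 20.9% of genes changed exactly 2-fold, which sit on its size bound, 89.6% of those changed 4-fold and 90.9% of those changed 8-fold. It called 0.0524% of the unchanged genes. Of 200 random lists of unchanged genes, 7% were said to stand apart. Variation between replicate libraries is unknown with 1 library per group, and whole reads were not recovered from the intervals. These shares are therefore not error rates of the calls made on the 2 libraries.

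Alternatives changed the pseudocount, the filter on low values, the scaling, the use of the intervals, the size rule, the status filter, the choice of row per symbol and the matching of random lists. Alternatives chosen after seeing the data removed the trend with GC content and transcript length (lowess, span 0.3), recentred the intervals on the FPKM, set the median difference to 0, or left out genes listed at 0. GC content and length were known for 97.7% of the genes tested. Calls without the GC and length trend used the adjusted difference for size but the deposited intervals, which keep that trend. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No column of values of the 2 tables was left unmapped.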

Results

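By its labels, the study profiled MCF-7 breast cancer cells with and without knockdown of CD24, in monolayer and in sphere culture. CD24 is a small surface glycoprotein whose low level is used to mark breast cancer stem cells. Of the study's 4 libraries, monolayer CD24KD and sphere WT are described here, each named by its label. Monolayer CD24KD had 12183 genes at 1 FPKM or more and sphere WT had 10404. No library had a replicate.

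CD24 was lower in the library labelled as its knockdown. Its transcript NM_013230, the one CD24 row in the tables, had 1.82 FPKM in monolayer CD24KD (95% interval 0.693 to 1.34) and 17.5 FPKM in sphere WT (10.9 to 16.1). Both FPKM lie above their own interval, and the intervals do not overlap. The difference was 6.56-fold on the scale of FPKM plus 1, or 2.71 on the log2 scale. It cannot be assigned to the knockdown, because the culture differs as well and monolayer CD24KD may hold other cells. The row lies on chromosome Y at 19611914 to 19614093 in hg18. CD24 has near-identical copies elsewhere in the genome, so reads of the copies cannot be told apart.

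Sphere WT was set against monolayer CD24KD to describe how the 2 libraries differ. Besides culture and knockdown, the cells themselves may differ, because monolayer CD24KD had transcripts of genes that MCF-7 is known to lack. Sphere WT had far higher epithelial, luminal, estrogen receptor, interferon and NF-kappaB target genes, while replication, mitosis and several mesenchymal genes were lower. Of 13418 genes tested, 2567 were higher in sphere WT, 4827 were lower and 6024 were neither. The median gene differed by -0.53 (log2), and median-of-ratios scaling placed sphere WT at -0.32 relative to monolayer CD24KD. Across the 9125 genes at 1 FPKM or more in both libraries, Spearman's rho was 0.637, computed across genes that are not independent replicates. The difference followed GC content across genes (rho 0.484): its median was -1.38 in the 1311 genes lowest in GC and 1.01 in the 1311 highest in GC. As deposited, 65.3% of called genes were lower, a share that depends on the centring: it was 56.2% with median-of-ratios scaling and 45.8% (3520 higher, 2980 lower) with the median difference set to 0. Without the trend with GC content and length, which also centres the differences, 2337 genes were higher and 2551 were lower, or 52.2% lower. The intervals in those calls were the deposited ones, so the counts are not free of the trend.

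**Figure D1:**
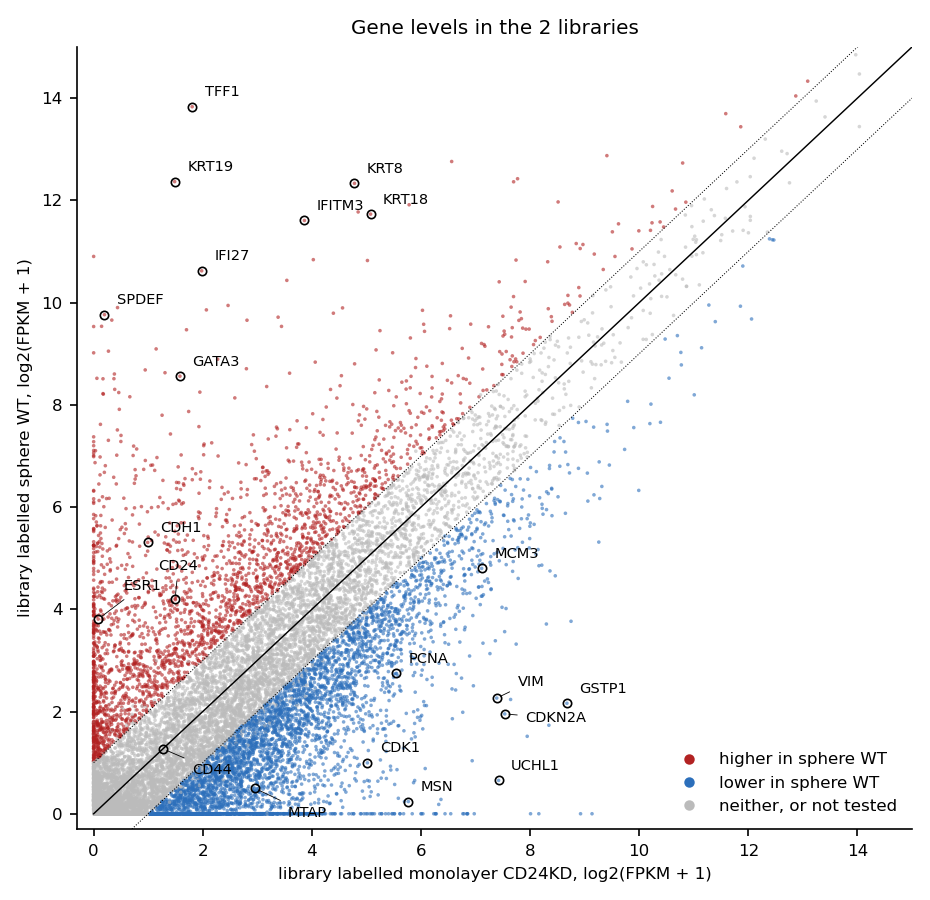
Each point is 1 gene, with log2(FPKM + 1) in monolayer CD24KD on the x axis and in sphere WT on the y axis. The solid line marks equal values, the dotted lines a 2-fold difference, red points are called higher in sphere WT and blue points lower. Small RNA genes are left out. TFF1 and KRT19 lie at the upper left, and VIM, GSTP1 and CDKN2A at the lower right.

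Epithelial junction and keratin genes were higher in sphere WT: 18 of 20 members were higher, 1 was lower and 1 was neither. The list's median difference was 5.85 (log2), at percentile 100 of the random lists. KRT19, a keratin of simple epithelia, had 1.80 FPKM in monolayer CD24KD and 5280 FPKM in sphere WT, the latter above its own 95% interval of 3940 to 4056. KRT8 had 26.5 FPKM and 5156 FPKM over its rows, a difference of 7.55 (log2). Its largest row alone was listed at 0 in monolayer CD24KD, so no size is given for that row. The tight junction gene CLDN3 had 0.259 FPKM and 806 FPKM, and the mucin MUC1 had 2.25 FPKM and 707 FPKM in the same order. CDH1, which encodes E-cadherin, had 0.987 FPKM (95% interval 0.599 to 0.984) in monolayer CD24KD and 38.6 FPKM (31.0 to 36.6) in sphere WT. Its row lies on chromosome 16 at 67328696 to 67426945. Of 12 luminal lineage genes, 10 were higher and 0 were lower in sphere WT, with a median of 5.40 at percentile 100. The transcription factor SPDEF had 0.147 FPKM in monolayer CD24KD and 868 FPKM in sphere WT, and GATA3, a luminal regulator, had 1.99 FPKM and 376 FPKM.

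Estrogen receptor genes were also higher in sphere WT: 16 of the 21 members with a value were higher, 3 were lower and 2 were neither, with a median of 2.31 at percentile 100. ESR1, the gene of estrogen receptor alpha on chromosome 6 at 152170507 to 152466101, had 0.0595 FPKM (95% interval 0.0362 to 0.129) in monolayer CD24KD and 13 FPKM (11.5 to 14.6) in sphere WT. TFF1, a secreted protein induced by estrogen, had 2.5 FPKM and 14577 FPKM, the latter above its own 95% interval of 9910 to 10224. TFF3 was listed at 0 in monolayer CD24KD and had 517 FPKM in sphere WT. The cyclin gene CCND1 had 2.5 FPKM in monolayer CD24KD and 91.7 FPKM in sphere WT, and CA12 had 1.54 FPKM and 37.6 FPKM.

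Mesenchymal genes were mostly lower in sphere WT: 10 of 16 members were lower, 3 were higher and 3 were neither, with a median of -1.79 at percentile 0.15. VIM, the intermediate filament vimentin on chromosome 10 at 17310264 to 17319598, had 167 FPKM (95% interval 196 to 206) in monolayer CD24KD and 3.8 FPKM (2.33 to 5.04) in sphere WT. The repressor gene SNAI2 had 9.82 FPKM and CDH2, N-cadherin, had 9.46 FPKM in monolayer CD24KD, and both were listed at 0 in sphere WT. S100A4 went the other way, with 4.26 FPKM in monolayer CD24KD and 75.5 FPKM in sphere WT. Of the 10 lower members, 7 were listed at 0 in sphere WT, so the median rests largely on values of 0.

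Genes that mark the MCF-7 line differed together with these groups. MTAP and CDKN2A lie in the part of 9p21 that MCF-7 is known to lack. MTAP, on chromosome 9 at 21792635 to 21855969, had 6.74 FPKM (95% interval 2.55 to 3.24) in monolayer CD24KD and 0.413 FPKM (0.131 to 0.686) in sphere WT. CDKN2A, whose longest row spans 21957751 to 21984490, had 184 FPKM (179 to 191) in monolayer CD24KD and 2.87 FPKM (1.87 to 4.64) in sphere WT. Of 12 genes picked from the 17q23 and 20q13 regions amplified in MCF-7, 9 were higher and 0 were lower in sphere WT. These genes were chosen after the tables were first seen. Of the 78 genes from 50 to 60 Mb on chromosome 17, 21 were higher and 25 lower. On chromosome 20, 30 of 78 genes from 40 to 50 Mb were higher and 14 lower. From 50 to 60 Mb there, 10 of 28 were higher and 4 lower. The medians of these 10 Mb windows without the GC and length trend were 0.50, 0.51 and 1.15.

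Breast cancer stem cell markers did not stand apart as a list: of 9 members with a value, 2 were higher in sphere WT, 4 were lower and 3 were neither, with a median of -0.86 at percentile 39.6 as deposited and 0.34 without the GC and length trend. CD44, the surface receptor paired with CD24 in stem cell sorting, had 1.41 FPKM in both libraries, and a difference of 1.15 (log2) without that trend, with overlapping intervals as deposited. EPCAM had 0.981 FPKM in monolayer CD24KD and 59.0 FPKM in sphere WT, and the chemokine receptor gene CXCR4 had 1.90 FPKM and 14.9 FPKM. PROCR was lower, with 5.32 FPKM in monolayer CD24KD and 0.837 FPKM in sphere WT. ALDH1A3 had 1.95 FPKM in monolayer CD24KD and was listed at 0 in sphere WT. Among 14 pluripotency and self-renewal factors, 3 were higher, 5 were lower and 6 were neither, with a median of -0.55 at percentile 54.3 as deposited and 0.15 without that trend. KLF4 had 1.5 FPKM in monolayer CD24KD and 21 FPKM in sphere WT, SALL4 had 0.158 FPKM and 5.21 FPKM, and ID4 had 33.0 FPKM and 0.346 FPKM. LIN28B had 9.15 FPKM in monolayer CD24KD and was listed at 0 in sphere WT.

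Interferon-stimulated genes were higher in sphere WT in 33 of 34 members and lower in 0, with a median of 3.14 at percentile 100. IFI27 had 2.94 FPKM in monolayer CD24KD and 1574 FPKM in sphere WT. The membrane antiviral genes IFITM3 and IFITM1 had 13.6 FPKM and 27.8 FPKM in monolayer CD24KD, against 3117 FPKM and 3499 FPKM in sphere WT. IFI6 had 31.4 FPKM and 1811 FPKM. HLA class I and antigen presentation genes were higher in 9 of 12 members and lower in 0, with a median of 2.12 at percentile 99.98. CD74, the invariant chain of class II molecules, had 0.0956 FPKM in monolayer CD24KD and 56.1 FPKM in sphere WT. TAPBP had 6.44 FPKM and 148 FPKM, HLA-E had 17.5 FPKM and 169 FPKM, and HLA-A had 54.8 FPKM and 321 FPKM.

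NF-kappaB targets were higher in 12 of 17 members and lower in 1, with a median of 2.88 at percentile 100. IER3 had 10.6 FPKM in monolayer CD24KD and 1383 FPKM in sphere WT, the cytokine gene LTB had 0.146 FPKM and 101 FPKM, BCL3 had 0.835 FPKM and 63.4 FPKM, and the adhesion receptor gene ICAM1 had 0.150 FPKM and 24.7 FPKM. ERK feedback and immediate early genes were higher in 15 of 22 members and lower in 2, with a median of 1.47 at percentile 100. JUNB had 5.96 FPKM in monolayer CD24KD and 417 FPKM in sphere WT, and DUSP4 had 0.427 FPKM and 28.0 FPKM. Of 6 mucin and sialic acid ligand genes with a value, 5 were higher and 0 were lower, with a median of 1.93 at percentile 99.8. MUC5B had 0.0554 FPKM in monolayer CD24KD and 38.2 FPKM in sphere WT.

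Replication genes were lower in sphere WT: 22 of 27 members were lower and 0 were higher, with a median of -2.35 at percentile 0. CDC6, a replication licensing factor, had 33.9 FPKM in monolayer CD24KD and 1.69 FPKM in sphere WT. DHFR had 44.0 FPKM and 3.94 FPKM, and CHAF1B had 19.5 FPKM and 0.476 FPKM. RFC4 had 47.9 FPKM in monolayer CD24KD and was listed at 0 in sphere WT. Mitosis genes were lower in 19 of 31 members and higher in 0, with a median of -1.36 at percentile 0.05. CDK1, the mitotic kinase, had 31.4 FPKM in monolayer CD24KD and 0.994 FPKM in sphere WT, and BUB1B had 23.2 FPKM and 1.69 FPKM. Without the trend with GC content and length, 22 replication genes were lower and 0 higher, with a median of -1.60, while 11 mitosis genes were lower, 2 were higher and 18 were neither, with a median of -0.67. Both lists still stood apart.

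Hypoxia targets were higher in 14 of 29 members and lower in 3, with a median of 0.75 at percentile 99.7. ANGPTL4 had 0.290 FPKM in monolayer CD24KD and 94.8 FPKM in sphere WT. CA9, a carbonic anhydrase induced by low oxygen, had 0.0160 FPKM and 15.1 FPKM. ANKRD37 had 1.63 FPKM and 33.8 FPKM. Without the GC and length trend this median was 1.94. Glycolysis genes were higher in 8 of 17 members and lower in 4, with a median of 0.96 at percentile 98.4. ALDOA had 364 FPKM in monolayer CD24KD and 4008 FPKM in sphere WT, and the lactate carrier gene SLC16A3 had 1.87 FPKM and 88.4 FPKM. LDHB had 485 FPKM in monolayer CD24KD and was listed at 0 in sphere WT. The glycolysis list no longer stood apart without the GC and length trend (percentile 95.2) or with the largest row per gene (percentile 97.2).

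Cytosolic heat shock genes were lower in 8 of 15 members and higher in 2, with a median of -1.39 at percentile 0.34. HSPA8, a constitutive chaperone, had 612 FPKM in monolayer CD24KD and 38.8 FPKM in sphere WT. HSPB1 went the other way, with 93.5 FPKM and 6936 FPKM, as did HSPA1A with 0.135 FPKM and 27.3 FPKM. Without the GC and length trend the list no longer stood apart (median -0.47, percentile 6.41).

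Of the 33 lists with enough members, 10 stood apart as higher in sphere WT and 4 as lower. Some lists share members, such as KRT8 and KRT19 in the epithelial and luminal lists and ALDOA in the hypoxia and glycolysis lists. The lists are therefore not independent of each other. After removal of the GC and length trend 17 stood apart, 12 of them in both analyses. The p53 targets were among the lists that stood apart then and not as deposited, with a median of 0.79 against 0.35. CDKN1A, a cell cycle inhibitor, had 11.1 FPKM in monolayer CD24KD and 392 FPKM in sphere WT, and GDF15 had 4.52 FPKM and 984 FPKM. The ATF4 and amino acid response list likewise stood apart as lower then and not as deposited, with medians of -0.53 and -0.76. PSAT1, an enzyme of serine synthesis, had 108 FPKM in monolayer CD24KD and 2.96 FPKM in sphere WT. DDIT3 was listed at 0 in monolayer CD24KD and had 154 FPKM in sphere WT.

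**Figure D2:**
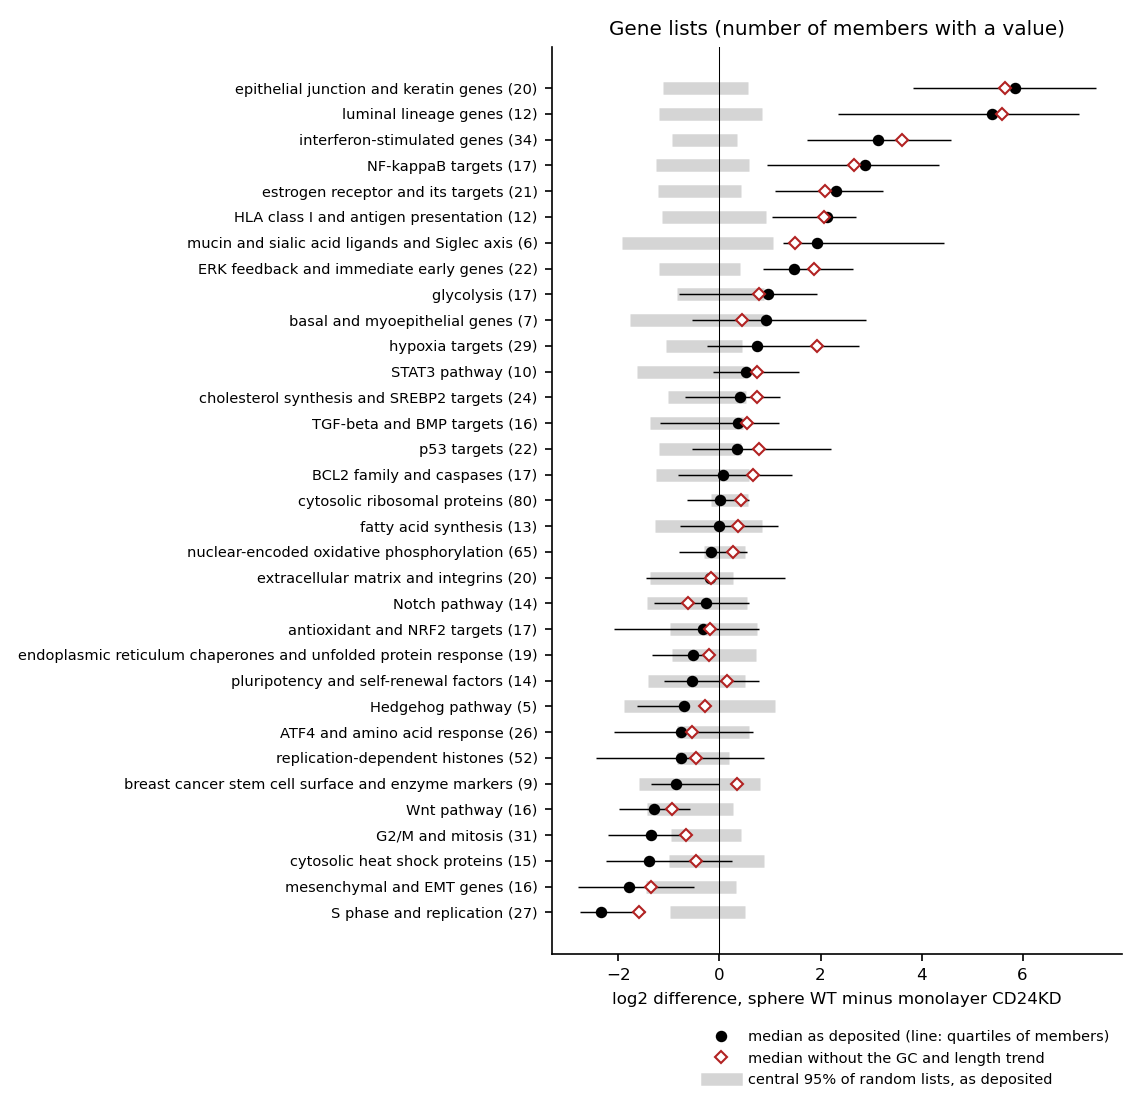
The x axis is the log2 difference, sphere WT minus monolayer CD24KD, and each row is 1 fixed gene list. Black points are medians as deposited with lines over the quartiles of the members, and open diamonds are medians without the GC and length trend. Grey bars hold the central 95% of random lists on the deposited differences, so they are no reference for the diamonds. Epithelial junction and keratin genes lie highest at 5.85, and replication genes lie lowest at -2.35.

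Lists of fibroblast, leukocyte and endothelial markers had few members with a value. Of 6 endothelial markers 0 reached 1 FPKM with a usable status, and the fibroblast list had 1 such gene, COL1A1, with 2.39 FPKM in monolayer CD24KD and 8.90 FPKM in sphere WT. The leukocyte list had 2 such genes. CD68 had 2.38 FPKM in monolayer CD24KD and 14 FPKM in sphere WT, and LYZ had 1.81 FPKM and 2.21 FPKM. Cytosolic ribosomal protein genes were neither higher nor lower in 55 of 80 members, with a median of 0.01 as deposited and 0.44 without the GC and length trend.

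The 10 largest differences toward sphere WT were those of TFF1, S100A9, KRT19, SPDEF, ADIRF, DSCAM-AS1, TSTD1, CLDN3, TFF3 and S100A7. S100A9, a calcium-binding protein of inflamed epithelia and myeloid cells, was listed at 0 in monolayer CD24KD and had 1913 FPKM in sphere WT, above its own 95% interval of 1115 to 1211. DSCAM-AS1, a long non-coding RNA, had 0.354 FPKM in monolayer CD24KD and 956 FPKM in sphere WT. Of the 9 reported genes with the largest differences the other way, 8 were listed at 0 in sphere WT. They are NME1, LDHB, HYPK, H3-3A, SERF2-C15ORF63, SIGMAR1, ATP2A1-AS1 and TCEAL8. NME1 had 561 FPKM in monolayer CD24KD, above its own 95% interval of 360 to 380. Its interval in sphere WT, 0.102 to 0.606, leaves out the 0 it is listed at. UCHL1, a ubiquitin hydrolase, had 171 FPKM in monolayer CD24KD, above its own 95% interval of 123 to 133, and 0.572 FPKM in sphere WT. A selection of genes above 0 in both libraries was added after the data were seen. Its reported genes with the largest differences toward monolayer CD24KD were UCHL1, SIAE, GSTP1, GPX1, AKR1B1, IRS4, HMGN5, CDKN2A and MSN. IRS4 had 81.5 FPKM in monolayer CD24KD and 0.214 FPKM in sphere WT. GSTP1, a glutathione transferase, had 408 FPKM in monolayer CD24KD, below its own 95% interval of 576 to 602, and 3.47 FPKM in sphere WT. MSN, the membrane linker moesin, had 53.5 FPKM and 0.180 FPKM.

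**Figure D3:**
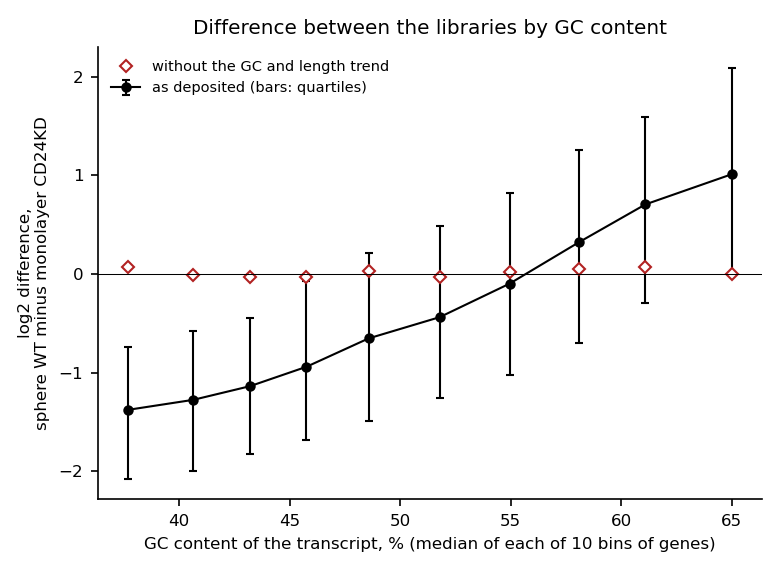
Genes were split into 10 bins by the GC content of their transcripts, given in percent on the x axis as the median of each bin. The y axis is the log2 difference, sphere WT minus monolayer CD24KD, with black points for medians as deposited, bars for quartiles and diamonds for medians after removal of the GC and length trend. The deposited medians go from -1.38 to 1.01.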

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

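No paired analysis was possible because each group has 1 library and no test was made. Alternatives without the GC and length trend, with recentred intervals, with the median difference set to 0 or without genes listed at 0 were chosen after seeing the data. The counts of 2567 genes higher and 4827 lower in sphere WT became 1651 and 2326 with a pseudocount of 5, and 1183 and 1830 with a 4-fold rule, since both ask for a larger change. With at least 5 FPKM in 1 library, 3198 genes were lower because fewer genes were tested. With the median difference set to 0, 2980 genes were lower and 3520 higher. Without the GC and length trend 2551 genes were lower, of which 2257 were lower as deposited. The other counts stayed within 1.5 times. Median-of-ratios scaling gave 3200 higher and 4102 lower, with 56.2% of called genes lower against 65.3%. The 106 called genes that were followed, among them all called genes named in the report and in the closing section, kept their direction under median-of-ratios scaling, a pseudocount of 0.1, the largest row per gene and removal of the trend, and all but COL1A1 without the trend (0.86) kept their call. CD44, called neither, went to 0.19 with median-of-ratios scaling and to 1.15 without the trend. With the largest row per gene 10 of the 106 moved by over 1.5 times, and 60 did so with a pseudocount of 0.1 and 55 without the trend. KRT8 moved the most with the largest row per gene, but that row was listed at 0 in monolayer CD24KD. The 14 lists that stood apart kept the sign of their median under each alternative that gave them a value, while 6 of the 19 others changed sign under at least 1. With at least 5 FPKM 29 lists had enough members, and without genes listed at 0 32 had. Glycolysis and heat shock genes no longer stood apart without the trend, and glycolysis also with the largest row per gene. Mesenchymal genes no longer stood apart without genes listed at 0, with a median of -0.51 at percentile 42.2. That alternative took out lower members only. It shows that the list's place rests on its values of 0, and cannot tell whether these are failed estimates. Lists also came to stand apart. With at least 5 FPKM these were p53 targets, TGF-beta targets and histones, and with the largest row per gene p53 and TGF-beta targets. Median-of-ratios scaling added basal genes, a pseudocount of 0.1 the STAT3 pathway, and matching on locus length cholesterol genes and histones. Leaving out genes listed at 0 added cholesterol genes and TGF-beta targets. Removing the trend added cholesterol genes, the ATF4 response, the Wnt pathway, p53 targets and histones. The depth is unknown, and its limit on low genes was not tested.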

Other observations

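The tests that used CDKN2A for cell division and IFNL1 for interferon, and the plain ratios of luminal genes, were chosen after their values were seen. The regional medians, and the removal of the GC and length trend, were chosen after that trend was seen, but the bounds for the adjusted medians were set before these were computed. Type III interferon genes were present in sphere WT: IFNL1 had 0.415 FPKM in monolayer CD24KD and 168 FPKM in sphere WT, IFNL2 had 0.0716 FPKM and 69.0 FPKM, and IFNL3 was listed at 0 and had 56.9 FPKM. These 3 genes are similar in sequence, and reads shared among them cannot be assigned to one of them. IFNB1 had 2.84 FPKM in monolayer CD24KD and 9.15 FPKM in sphere WT. Neurofilament genes were higher in monolayer CD24KD, where NEFL had 14.5 FPKM, NEFM 11.9 FPKM and INA 8.44 FPKM. In sphere WT NEFL and INA were listed at 0 and NEFM had 0.215 FPKM. Of the 12 genes picked from the 17q23 and 20q13 regions, 9 were higher in sphere WT. Among them, ZNF217 had 1.63 FPKM in monolayer CD24KD and 50.5 FPKM in sphere WT, and NCOA3 had 1.90 FPKM and 28.0 FPKM.

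Differences were also grouped by position. Of 223 autosomal windows of 10 Mb with 20 or more genes, 14 had a median in the top 0.1% of matched random lists and 14 in the bottom 0.1%. Random draws of genes would give 0.223 at each end. Genes that lie together can vary together, so the excess over that number cannot be assigned to a cause. The window medians are without the GC and length trend. On chromosome 8 the window from 120 to 130 Mb (hg18) had a median of 1.33 over 32 genes, of which 12 were called higher in sphere WT and 8 lower. On chromosome 20 the window from 50 to 60 Mb had 1.15 over 28 genes, with 10 higher and 4 lower. On chromosome 13 the window from 70 to 80 Mb had -1.52 over 24 genes, with 0 higher and 21 lower. On chromosome 1 the window from 220 to 230 Mb had -1.34 over 66 genes, with 4 higher and 49 lower. These calls are on the deposited values, with the trend kept.

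Luminal, keratin and estrogen receptor genes were far lower, and vimentin higher, in monolayer CD24KD. MCF-7 cells changed only by culture and CD24 knockdown are argued against by MTAP at 6.74 FPKM and CDKN2A at 184 FPKM there, since MCF-7 is known to have lost both genes; scaling and the GC and length trend are argued against by the luminal median, as monolayer minus sphere, of -5.72 after median-of-ratios scaling and -5.59 without the trend. A library of cells other than MCF-7 under the monolayer CD24KD label is a candidate explanation, with MTAP at 0.413 FPKM (95% interval 0.131 to 0.686) in sphere WT. CDKN2A in sphere WT, at 2.87 FPKM (1.87 to 4.64), is above the 0.5 FPKM bound set for MCF-7 cells and meets the bound for presence, so the same reading is not clean for sphere WT either. For MCF-7 RNA diluted by other RNA, the interquartile range of the luminal differences was 4.77 against a bound of 2 set in advance. It was 3.49 for the plain log2 ratios of the 8 members at 1 FPKM or more in both libraries. Those members had from 0.0341% to 50% of their sphere WT level in monolayer CD24KD. These ranges cannot decide, since the pseudocount widens the first and the other RNA may hold some of these transcripts. Of 10 luminal members at 10 FPKM or more in sphere WT, 6 had under 1% of that level in monolayer CD24KD. This argues against a large share of RNA like that of sphere WT, though a trace of MCF-7 RNA is not excluded.

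Marker lists of 13 other cell or tissue types were read in both libraries, and they do not settle which cells monolayer CD24KD holds. At 5 FPKM or more in monolayer CD24KD were 0 of 11 erythroid, 0 of 10 T cell, 0 of 9 B and plasma cell, 0 of 9 myeloid, 0 of 7 melanocyte, 0 of 8 hepatocyte, 0 of 6 prostate and 0 of 6 kidney markers. The neuronal list had 3 of 9, and the mesenchymal breast line, intestinal, muscle and germ line lists had 1 each. In sphere WT the same bound was reached by 2 erythroid markers, by 2 germ line markers and by 1 each of the B and plasma cell, myeloid, neuronal, melanocyte, muscle and kidney lists. At 1 FPKM or more, the mesenchymal breast line list had 6 of 10 in monolayer CD24KD and 2 in sphere WT. In the same order neuronal markers had 4 and 1, muscle 2 and 1, intestinal 1 and 0, erythroid 2 and 3, and hepatocyte 1 and 3. The other lists had equal counts in both libraries at that bound.

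Replication and mitosis genes were lower in sphere WT. The GC and length trend is argued against as the whole cause for replication genes, whose median without it was -1.60 (quartiles -1.92 and -1.20) against -2.35 as deposited. For mitosis genes it stays open, since their median went from -1.36 to -0.67 (quartiles -1.15 and 0.10), between the bounds set in advance. Fewer dividing MCF-7 cells in spheres cannot be told apart from a difference between cell lines, because CDKN2A at 184 FPKM in monolayer CD24KD leaves open that this library holds other cells.

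Interferon-stimulated genes were higher in sphere WT. The GC and length trend is argued against, since the median without it was 3.62 (quartiles 2.54 and 4.78). Interferon made by the cells of sphere WT is a candidate explanation, with IFNL1 at 168 FPKM there. Culture and knockdown, in which the 2 libraries differ at once by their labels, and a possible difference between cell lines remain open.

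Listed zeros fell in both libraries. Of the genes tested, 1253 were listed at 0 in sphere WT and 249 in monolayer CD24KD. Among higher genes, and leaving out small RNA genes, 21 genes at 50 FPKM or more in monolayer CD24KD were listed at 0 in sphere WT, and 17 genes at 50 FPKM or more in sphere WT were listed at 0 in monolayer CD24KD. PDIA3, a chaperone that cells generally need, had 75.9 FPKM in monolayer CD24KD and was listed at 0 in sphere WT.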
